A study of Homo sapiens with 18 samples.

How the data were processed

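Poly(A)-selected RNA from the human melanoma line WM989 was sequenced in 18 libraries, 3 for each of 6 groups formed by treatment (DMSO or 4 µM EPZ5676 for 7 days) and sort (bulk, NGFR and EGFR high, NGFR and EGFR low). The deposited table held raw counts per Ensembl gene and library, made by the authors. Reads had been aligned with STAR and counted with HTSeq on hg19, per the submitters' processing notes, which give no versions, strand setting or annotation release. The table listed 63677 genes and 5 HTSeq summary lines per library, and 0 sample names failed to match a sample. Of the genes, 52181 were named from a current name table, 345 only from GENCODE 29, and 11151, with 0.922% of the gene counts, stayed unnamed. Reads on no feature made up 12.8% to 28.65% and ambiguous reads 6.07% to 7.71% of each library's total; the 5 summary lines were left out of the tests. Mitochondrially encoded genes had 0 counts in all 18 libraries. Gene counts per library ran from 13383741 to 26311674, and 0 pairs of libraries were identical. No genome positions are given, since the counts were made on hg19 and the reference at hand is a later build.

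Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 18121, and scaled with TMM factors. A quasi-likelihood model with robust estimation was fitted to the means of the 6 groups over all 18 libraries. The 6 comparisons were EPZ5676 against DMSO in bulk, in high and in low cells, high against low cells under DMSO and under EPZ5676, and the interaction of treatment and sort. P-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05, and a second count took genes that also changed at least 2-fold. Standard errors of log2 fold changes came from the quasi-likelihood F statistic. Log2 CPM for the principal components and correlations used a prior count of 2. A group whose libraries were all at 0 was set to a bound of 3 counts, and list medians are also given with such genes at their bound.

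There were 31 gene lists fixed by name, and the 28 with at least 5 tested genes were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. They covered DOT1L and its complex partners, HOXA and MEIS genes, rare-cell resistance markers, pigmentation, neural crest-like and undifferentiated melanoma states, AP-1 genes, YAP/TEAD targets, MAPK output, TGF-beta response, extracellular matrix, receptor tyrosine kinases, DNA replication, mitosis, p53 targets, interferon response, antigen presentation, NF-kB and cytokines, sterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, amino acid and ER stress, heat shock, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones and neuronal genes. Markers of fibroblasts, keratinocytes, leukocytes and endothelial cells served as lists of other cell types. Of the 8 tested fibroblast markers, COL1A1, COL1A2 and COL3A1 are also in the extracellular matrix list and PDGFRA in the receptor list, which also holds the endothelial marker KDR.

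Named genes followed a rule. NGFR, EGFR and DOT1L were always named. In each direction the rule took the 10 called genes with the largest log2 fold change among those with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, leaving out clone-named and antisense transcripts and pseudogenes; for the interaction the overlap was not asked for. From each list that passed, or that held at least 3 changed genes, up to 4 members with the smallest p were taken, fewer where a list repeats a family. Some genes that the rule takes are not described. The lists of DOT1L and its complex partners (DOT1L partners below), pigmentation, resistance markers and other cell types were described whether or not they passed.

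The groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined. These alternatives were RLE factors or library size alone for scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, estimation that was not robust, a fit of only the groups compared, the replicate number as a block, a prior count of 0.5, the 100 genes with the smallest p per direction as sets, fry or an estimated inter-gene correlation for lists, and leaving out each library in turn. Chosen after seeing the data were the no-feature share as a covariate, leaving out the 6 libraries with a share over 16%, leaving DMSO bulk replicate 1 out of the shared spread, and combinations of these. The pipeline was tested on simulated data, with 67, 67 and 66 genes changed 1.5, 2 and 4-fold. A raised list was called and 0 of 20 unchanged lists were. Counts were drawn independently for each gene around a common mean, without an outlying library or a difference in the no-feature share. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.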

Results

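RNA was measured by poly(A)-selected sequencing in 18 libraries of WM989, an established human melanoma cell line. Cells had been treated for 7 days with DMSO, the solvent control, or with 4 µM EPZ5676, an inhibitor of the histone H3 methyltransferase DOT1L. For each treatment there were 3 bulk libraries, 3 libraries of cells sorted for high surface NGFR and EGFR, and 3 libraries of cells sorted for low levels of both. The libraries held 13383741 to 26311674 gene counts. Levels are normalised read counts scaled to library size (CPM) as mean ± SD (n = 3 libraries), and fold changes are on the log2 scale ± SE. Each fold change uses 3 libraries per group. Its SE and p-value rest on a spread estimated over all 18 libraries, with DMSO bulk replicate 1 among them. Replicates are labelled as separate samples, but nothing says that they came from separate cultures, so each p-value measures only the spread between these samples. Adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction.

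The first principal component held 66.4% of the variance and set the sorts apart. DMSO high libraries lay between -87.6 and -86.7, EPZ5676 high libraries between -77.3 and -72.2, EPZ5676 low libraries between 51.3 and 52.4, and DMSO low libraries between 60.1 and 60.8. Bulk libraries lay near the low sort, except DMSO bulk replicate 1 at -30.5, against 45.1 and 44.2 for the other DMSO bulk libraries. The second component held 7.53% and set apart 6 libraries in which 18.88% to 28.65% of the assigned and unassigned reads fell on no annotated feature, against 12.8% to 15.17% in the other 12. Of these 6, 5 were EPZ5676 libraries (bulk replicates 1 and 3, high replicates 1 and 2, low replicate 1) and 1 was DMSO high replicate 3. Among the other 12 libraries the second component also set treatments apart, from 1.6 to 10.7 in EPZ5676 and from 13.2 to 25.1 in DMSO libraries.

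**Figure D1:**
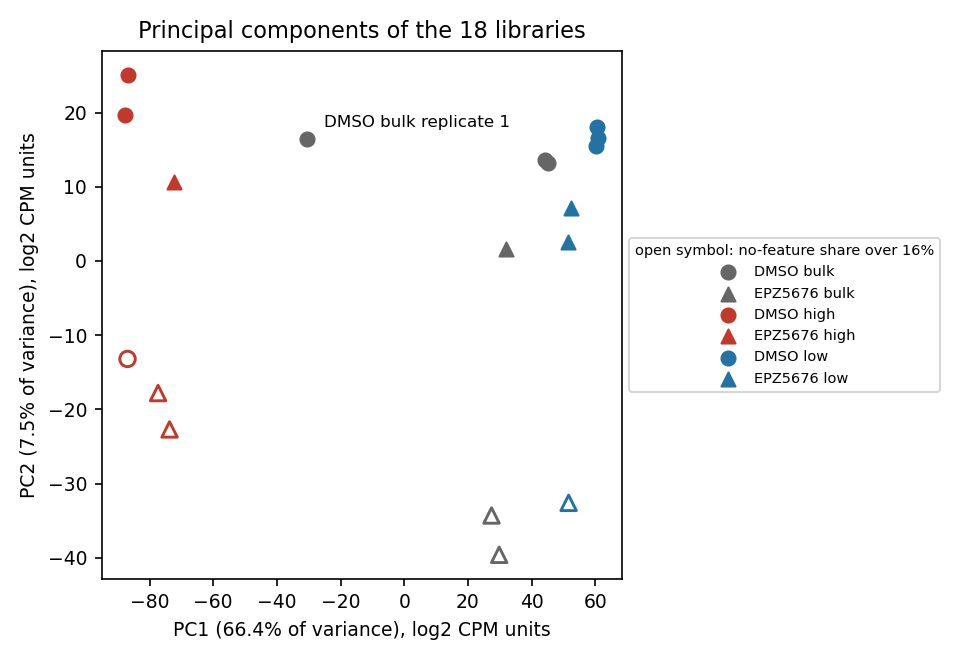
First and second principal components of log2 CPM for the 18 libraries, by treatment (shape) and sort (colour), with open symbols for the 6 libraries with more than 16% of reads on no feature. DMSO bulk replicate 1 lies at -30.5 on the first component, between the high and low sorts.

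The comparison of high with low cells under DMSO asks which genes set apart the cells with high NGFR and EGFR. NGFR (ENSG00000064300) and EGFR (ENSG00000146648), the genes of the sort, stood at 572 ± 40.8 and 75.9 ± 8.72 CPM in high cells and at 1.00 ± 0.527 and 2.79 ± 0.612 CPM in low cells, which checks the labels and is no finding. High cells held RNA of fibrillar collagens and of a collagen-binding integrin that low cells nearly lacked. COL1A1 stood at 930 ± 170 CPM against 2.08 ± 0.677 (log2 fold change 8.81 ± 1.21, adjusted p = 3.84e-05). COL5A1 stood at 78.0 ± 7.7 against 0.176 ± 0.0765 (8.74 ± 1.17), and ITGA11 at 66.2 ± 9.35 against 0.143 ± 0.0822 (8.78 ± 1.24). IGFN1 was higher by 9.37 ± 1.32. Melanocyte genes went the other way: DCT, an enzyme of melanin synthesis, stood at 59.2 ± 3.07 CPM in high and 1050 ± 39.9 in low cells (-4.15 ± 0.28, adjusted p = 7.01e-08). MITF, the transcription factor that directs melanocyte identity, stood at 193 ± 11.1 against 596 ± 39.8 CPM (-1.63 ± 0.10, adjusted p = 2.27e-09). TRPM1 (-4.45), RLBP1 (-4.27), POU3F1 (-4.32) and PRDM7 (-4.76) were also among the genes with the largest negative changes.

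All 15 rare-cell resistance markers, genes known to mark rare melanoma cells that survive targeted therapy, were higher in high cells (median 3.91, adjusted p = 3.59e-08, or adjusted p = 0.265 with an estimated correlation). Among them were FGFR1 (233 ± 11.1 against 51.4 ± 2.82 CPM), NT5E (269 ± 19.9 against 39.8 ± 1.85) and PDGFC (40.3 ± 0.854 against 3.98 ± 0.792). Of 25 pigmentation genes, 20 were lower and 2 higher (median -1.53, adjusted p = 2.54e-12, or adjusted p = 0.142 with an estimated correlation), among them SLC24A5 (-2.07 ± 0.12) and CAPN3 (-4.57 ± 0.35). Of 18 genes of the undifferentiated melanoma state, 17 were higher and 0 lower (1 lower when adjusted over the list alone; median 3.49, adjusted p = 0.265 with an estimated correlation), such as ZEB1 (2.04 ± 0.17) and TCF4 (2.93 ± 0.26). Of 30 extracellular matrix genes, 26 were higher and 2 lower (median 3.07, adjusted p = 0.265 with an estimated correlation): LAMB1 stood at 1010 ± 38.8 against 389 ± 3.03 CPM and MMP14 at 1540 ± 10.7 against 758 ± 14.3, while SPARC was lower (-0.48 ± 0.05). Fibroblast markers, a list fixed as a sign of other cells, were higher for 7 of 8 genes (median 5.62, adjusted p = 0.00862, or adjusted p = 0.352 with an estimated correlation). FAP (8.43 ± 1.04) and PDGFRA (6.03 ± 0.77) were among them, and LUM was lower (-1.09 ± 0.14).

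Signalling lists also passed upward in high cells, with adjusted p = 0.265 with an estimated correlation for those from AP-1 to NF-kB genes and 0.28 for interferon genes. Of 23 AP-1 and immediate early genes, 19 were higher and 3 lower (median 2.17). IER2 was at 1.53 ± 0.10 and KLF6 at 1.38 ± 0.12, while MYC was lower at 212 ± 35.3 against 633 ± 59.0 CPM. Of 22 YAP/TEAD targets, 18 were higher and 1 lower (median 1.58). Among them were AMOTL1 (1.45 ± 0.15) and GADD45A (1.11 ± 0.06). Of 20 MAPK output genes, 17 were higher and 3 lower (median 1.14). DUSP5 (1.01 ± 0.07) and SPRY1 (0.99 ± 0.09) were higher and ETV4 lower (-0.88 ± 0.08). Of 22 TGF-beta response genes, 19 were higher and 0 lower (median 1.77). Among them were TGFBI (4.21 ± 0.47) and LTBP3 (1.51 ± 0.13). Of 36 receptor tyrosine kinases and ligands, 27 were higher and 5 lower (median 2.44). BDNF was higher (5.83 ± 0.65) and ERBB3 lower (-1.25 ± 0.07). Of 20 NF-kB and cytokine genes, 17 were higher and 1 lower (median 3.10, or 3.07 with genes at 0 counts in a group set to their bound). IRAK2 (2.29 ± 0.20) and NFKBIA (1.26 ± 0.09) were among them. Of 37 interferon response genes, 26 were higher and 4 lower (median 1.09). RSAD2 (3.49 ± 0.37) and IFI44 (1.62 ± 0.14) were higher and USP18 lower (-1.06 ± 0.14). Of 52 mitosis genes, 41 were higher and 2 lower (median 0.57, adjusted p = 5.8e-12, or adjusted p = 0.253 with an estimated correlation). TOP2A, which untangles DNA, stood at 493 ± 18.5 against 217 ± 8.9 CPM, and KIF23 (0.87 ± 0.05), UBE2C (1.26 ± 0.08) and HJURP (1.36 ± 0.09) were higher as well. The 41 genes of DNA replication were not called as a list (18 higher, 14 lower, median 0.02, or -0.05 when scaled by library size, adjusted p = 0.633).

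Lower in high cells were 24 of 32 oxidative phosphorylation genes, with 1 higher (median -0.45, adjusted p = 0.265 with an estimated correlation): ATP5F1B stood at 632 ± 32.1 against 1100 ± 68.4 CPM, and PPARGC1A, a coactivator that drives mitochondrial genes, at 4.46 ± 0.616 against 16.5 ± 1.93. Of 50 ribosomal protein genes, 31 were lower and 0 higher (median -0.30, adjusted p = 0.000223, or adjusted p = 0.412 with an estimated correlation), such as RPL5 (-0.62 ± 0.07) and RPL8 (-0.54 ± 0.06). Antigen presentation (12 of 21 higher, 4 lower, median 0.53), sterol synthesis (12 of 25 higher, 4 lower, median 0.22) and neuronal genes (11 of 15 higher, 2 lower, median 1.55) also passed. With an estimated correlation their adjusted p-values were 0.265, 0.508 and 0.412. DOT1L (ENSG00000104885) was higher in high cells (208 ± 11 against 125 ± 1.15 CPM, 0.73 ± 0.07, adjusted p = 1.52e-08). The list of DOT1L and its complex partners was not called (4 of 9 higher, 1 lower, adjusted p = 0.365). In it AFF3 (0.45 ± 0.09) and AFF1 (0.44 ± 0.09) were higher, and the list's median of -0.02 and mean of 0.19 differed in sign. The neural crest list was not called either (8 of 17 higher, 7 lower, median -0.02, mean 1.13). Of 6 endothelial markers, 4 were higher and 1 lower (median 1.9, adjusted p = 0.267), with VWF at 2.14 ± 0.24 and EGFL7 at -1.24 ± 0.12.

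In all, 10199 of 18121 tested genes differed, 5355 higher and 4844 lower in high cells (4746 and 5564 when scaled by library size alone), and 2321 were at least 2-fold higher and 1095 at least 2-fold lower. When adjusted over the list alone, 20 against 19 TGF-beta genes, 42 against 41 mitosis genes and 13 against 12 sterol genes were higher, and 25 against 24 oxidative phosphorylation genes lower. All 57 called genes named for this comparison kept their call with each single library left out. All 18 lists that passed had adjusted p-values between 0.142 and 0.508 with an estimated correlation. In every comparison that correlation comes from the spread of all 18 libraries, with DMSO bulk replicate 1 among them, also where bulk is not compared. It was estimated again without that library for the bulk comparison only. With a known change of 1.5, 2 or 4-fold put into simulated counts, the test found 61.2%, 65.7% and 92.4% of the genes changed, with 3.31% false calls. These shares, and those for the other comparisons, need not hold for the real libraries, since the simulation had no outlying library and no correlation between genes.

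The same comparison under EPZ5676 asks whether the sorted populations still differed after DOT1L inhibition. They did for 8858 genes, 4668 higher and 4190 lower in high cells (4067 and 4931 when scaled by library size alone), of which 1802 and 879 changed at least 2-fold. NGFR stood at 727 ± 70.6 against 3.85 ± 2.91 CPM and EGFR at 62.5 ± 6.58 against 4.59 ± 0.28, which again checks the labels and is no finding. ITGA11 (7.98 ± 1.22), IGFN1 (7.53 ± 1.18), the cytokine IL11 (7.5 ± 1.26) and COL5A1 (7.36 ± 1.12) were higher in high cells. The melanosome gene PMEL stood at 890 ± 61.2 against 10400 ± 33.1 CPM (-3.55 ± 0.26, adjusted p = 3.06e-07), and MITF at 239 ± 20.2 against 575 ± 8.74 (-1.27 ± 0.10, adjusted p = 6.88e-08). NMRK2 (-5.05 ± 0.46), PLB1 (-4.13 ± 0.55), TRPM1 (-3.84 ± 0.33), SYT7 (-3.82 ± 0.45) and RLBP1 (-3.78 ± 0.35) were lower.

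Under EPZ5676 all 15 resistance markers were again higher (median 3.43, adjusted p = 0.199 with an estimated correlation), such as FOSL1 (511 ± 37.2 against 108 ± 6.79 CPM) and NT5E (2.54 ± 0.29). Of 25 pigmentation genes, 19 were lower and 1 higher (median -1.44, adjusted p = 1.54e-13, or adjusted p = 0.0861 with an estimated correlation), with SLC24A5 at -1.63 ± 0.12. Medians were 3.52 for the undifferentiated state (16 of 18 higher, with TCF4 at 2.60 and ZEB1 at 1.64), 2.83 for extracellular matrix (26 of 30), 1.73 for AP-1 genes (19 of 23), 1.5 for YAP/TEAD targets (18 of 22), 0.91 for MAPK output (16 of 20, with DUSP5 at 1.2) and 1.71 for TGF-beta genes (18 of 22, with TGFBI at 5.93). They were 2.03 for receptor tyrosine kinases (27 of 36), 1.31 for interferon genes (25 of 37), 0.32 for antigen presentation (11 of 21), 2.06 for NF-kB genes (18 of 20), 1.27 for neuronal genes (11 of 15) and 0.45 for mitosis (41 of 52, with KIF23 at 0.73 and UBE2C at 1.13). Lower in these lists were 1 extracellular matrix, 4 AP-1, 3 MAPK output, 5 receptor and 2 interferon genes. So were 3 antigen presentation, 1 NF-kB, 2 neuronal and 2 mitosis genes. With an estimated correlation the adjusted p-values of these lists were 0.247 for antigen presentation, 0.22 for neuronal genes and 0.199 for the others. Fibroblast markers were higher for 7 of 8 (adjusted p = 0.224 with an estimated correlation, median 5.88, or 5.13 with a gene at 0 counts set to its bound), and 24 of 32 oxidative phosphorylation genes were lower (median -0.44, adjusted p = 0.199 with an estimated correlation), such as ATP5F1B (-0.68 ± 0.07) and PPARGC1A (-1.91 ± 0.15). The DNA replication list passed here (24 of 41 higher, 5 lower, median 0.16, adjusted p = 0.000342, or adjusted p = 0.199 with an estimated correlation). Ribosomal proteins (16 of 50 lower, median -0.10, adjusted p = 0.0735), sterol synthesis (adjusted p = 0.0923), endothelial markers (1 of 6 higher, 1 lower, adjusted p = 0.677) and DOT1L partners (3 of 9 higher, 2 lower, adjusted p = 0.593) did not. DOT1L itself was higher in high cells (0.64 ± 0.07, adjusted p = 1.82e-07). The 17 lists that passed had adjusted p-values between 0.0861 and 0.247 with an estimated correlation. Known changes of 1.5, 2 and 4-fold were found for 56.7%, 59.7% and 83.3% of genes, with 2.92% false calls. All 25 called genes named here kept their call with each single library left out; without the 6 libraries with a high share of reads on no feature, 4176 genes differed.

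**Figure D2:**
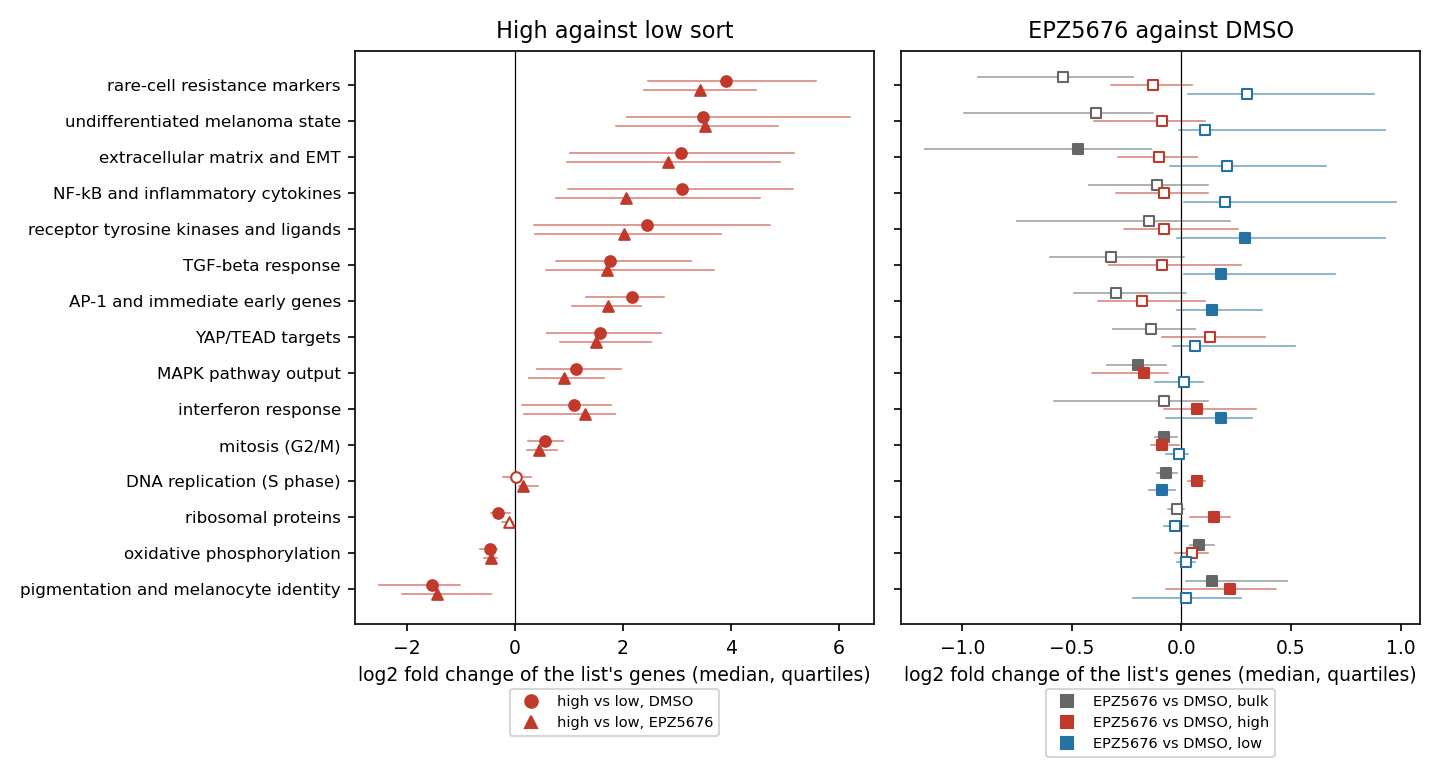
Median log2 fold change (symbols) and quartiles (bars) of 15 gene lists, high against low sort on the left and EPZ5676 against DMSO on the right; filled symbols passed camera with the preset correlation. Rare-cell resistance markers had medians of 3.91 and 3.43 between the sorts, and pigmentation genes -1.53 and -1.44.

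The comparison of EPZ5676 with DMSO in high cells asks what DOT1L inhibition changed in the NGFR- and EGFR-high population. Some melanocyte genes rose with EPZ5676. DCT rose from 59.2 ± 3.07 to 153 ± 10.3 CPM (1.37 ± 0.25, adjusted p = 0.0128), the endothelin receptor gene EDNRB from 19.4 ± 1.59 to 32.8 ± 2.16 (0.76 ± 0.12, adjusted p = 0.00104), and CAPN3 by 2.23 ± 0.43. A2M, a secreted protease inhibitor, rose from 102 ± 4.41 to 236 ± 7.0 CPM (1.2 ± 0.14, adjusted p = 0.000412), and TMC8 (ENSG00000167895) from 1.42 ± 0.27 to 5.2 ± 0.425 (1.89 ± 0.22, adjusted p = 4.18e-05). CYP26B1, which breaks down retinoic acid, rose by 1.13 ± 0.14, PTPRZ1 by 1.16 ± 0.15, COL12A1 by 1.17 ± 0.21, TGFBI by 1.15 ± 0.30 and the WNT inhibitor DKK1 by 2.65 ± 0.63. Lower with EPZ5676 were the laminin-binding integrin ITGA7 (84.1 ± 10.3 to 43.2 ± 2.13 CPM, -0.96 ± 0.11, adjusted p = 8.71e-05), ABCA1 (-0.76 ± 0.14), RGS17 (-0.65 ± 0.12), UHRF2 (-0.65 ± 0.15) and NR6A1 (-0.64 ± 0.12). NGFR (0.34 ± 0.85, adjusted p = 0.897), EGFR (-0.28 ± 0.30, adjusted p = 0.727) and DOT1L (-0.18 ± 0.07, adjusted p = 0.164) were not called. NGFR stood at 563, 537 and 617 CPM in DMSO and at 767, 768 and 645 in EPZ5676 high libraries, without overlap. Its SE rests on the spread shared by all 18 libraries, with DMSO bulk replicate 1 among them. Cells were sorted on NGFR and EGFR, so their levels within the high or low sort depend on the sort as well. Low cells in the EPZ5676 high sort were not excluded, and they would raise genes that low cells hold more of, such as DCT and CAPN3. The 1095 genes at least 2-fold lower in DMSO high than low cells had a median change of 0.35 here, with 14.2% below 0. These genes were chosen partly on the same DMSO high libraries. The rise of melanocyte genes thus cannot be read as DOT1L inhibition alone.

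Of 25 pigmentation genes, 4 rose and 1 fell in high cells (8 and 1 when adjusted over the list alone; median 0.22, adjusted p = 0.000293, or adjusted p = 0.513 with an estimated correlation). GPNMB was up (0.31 ± 0.07) and MLPH down (-0.28 ± 0.05). Low cells in the EPZ5676 high sort could also raise this list, since 20 of its 25 genes were lower in DMSO high than low cells. Of 17 neural crest genes, 4 rose and 0 fell (5 and 0 when adjusted over the list alone; median 0.17, adjusted p = 0.00363, or adjusted p = 0.513 with an estimated correlation). They were the integrins ITGA4 (0.42 ± 0.05) and ITGA6 (0.29 ± 0.06), S100B (0.38 ± 0.07) and ERBB3 (0.29 ± 0.07). Of 20 MAPK output genes, 2 fell and 0 rose (5 and 0 when adjusted over the list alone; median -0.17, adjusted p = 0.000293). These were the feedback inhibitors DUSP4 (1080 ± 30.8 to 757 ± 51.2 CPM) and SPRY1 (146 ± 1.21 to 101 ± 9.91). Of 41 DNA replication genes, 3 rose (8 when adjusted over the list alone; median 0.07, adjusted p = 0.00138). They were UNG (0.33 ± 0.06), DTL (0.27 ± 0.07) and EXO1 (0.23 ± 0.06). In turn 2 of 52 mitosis genes fell (4 when adjusted over the list alone; median -0.09, adjusted p = 0.000293), KIF23 (-0.25 ± 0.05) and ANP32E (-0.26 ± 0.06). Of 50 ribosomal protein genes, 5 rose (20 when adjusted over the list alone; median 0.15, adjusted p = 4.59e-06), such as RPL6 (0.30 ± 0.06) and RPL11 (0.31 ± 0.07). Of 29 glycolysis and hypoxia genes, 3 fell (5 fell and 1 rose when adjusted over the list alone; median -0.09, adjusted p = 0.0161), PDK1 (-0.36 ± 0.07), PFKL (-0.28 ± 0.05) and P4HA1 (-0.27 ± 0.05). Of 15 neuronal genes, 2 rose (4 when adjusted over the list alone; median 0.33, adjusted p = 0.000753), NRXN3 (0.82 ± 0.15) and DCX (1.41 ± 0.30). Each of these lists from MAPK output on had an adjusted p = 0.513 with an estimated correlation. Without the 6 libraries with a high no-feature share 4 lists passed, all upward, and none of the 3 downward lists did.

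Of 37 interferon genes, 3 rose in high cells (3 when adjusted over the list alone), OAS3 (0.29 ± 0.07), CMPK2 (0.67 ± 0.17) and IFITM2 (0.83 ± 0.22). The list's median was 0.07 (adjusted p = 0.047, or adjusted p = 0.899 with an estimated correlation). With the replicate number as a block it no longer passed (adjusted p = 0.0625). The amino acid and ER stress list held 6 genes that rose and 2 that fell of 30 (9 and 3 when adjusted over the list alone; median 0.01, adjusted p = 0.314). The chaperone genes CALR (0.25 ± 0.05) and PDIA4 (0.22 ± 0.05) and the serine enzyme SHMT2 (0.25 ± 0.05) rose, and CEBPB fell (-0.35 ± 0.07). Resistance markers (0 of 15 called, median -0.13, adjusted p = 0.521), DOT1L partners (0 of 9, median -0.09, adjusted p = 0.588) and endothelial markers (0 of 6, median 0.15, adjusted p = 0.615) were not called. Among 8 fibroblast markers 1 rose (adjusted p = 0.456), and the list's median of -0.22 and mean of -0.04 had the opposite sign to its test. In all, 543 genes changed, 354 higher and 189 lower, with 53 and 5 at least 2-fold. The spread behind this test is shared by all 18 libraries: without DMSO bulk replicate 1, which is not part of the comparison, 2018 genes changed, 1099 higher and 919 lower, including all 543. With the no-feature share as a covariate 450 of the 543 kept their call. Without the 6 libraries with a high share EPZ5676 high cells were 1 library, so that fit does not weigh the calls. Of the 42 called genes named for this comparison, 24 kept their call with each single library left out, among them TMC8, A2M, ITGA7, EDNRB, DUSP4 and SPRY1, while DKK1, TGFBI, UHRF2, CMPK2 and IFITM2 lost it whichever library was left out. Known changes of 1.5, 2 and 4-fold were found for 38.8%, 67.2% and 84.8% of genes, with 5.22% false calls.

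The comparison of EPZ5676 with DMSO in low cells asks the same of the NGFR- and EGFR-low population. CD22 (ENSG00000012124), known as a B cell surface receptor, rose from 9.03 ± 1.51 to 21.3 ± 1.83 CPM (1.24 ± 0.13, adjusted p = 2.83e-05). TRIM67 (1.18 ± 0.19), SCUBE2 (1.09 ± 0.18), EFHD1 (1.08 ± 0.20), PLEKHA7 (1.07 ± 0.19), NMRK2 (1.56 ± 0.33) and ZNF114 (1.14 ± 0.26) also rose. RNF182 fell from 33.9 ± 0.236 to 20.7 ± 0.613 CPM (-0.71 ± 0.08, adjusted p = 4.73e-05) and SCRN1 from 142 ± 3.26 to 104 ± 5.89 (-0.45 ± 0.06, adjusted p = 0.000675). The neural transcription factor POU3F2 (-0.44 ± 0.08), the serotonin receptor HTR7 (-0.46 ± 0.08), the ephrin EFNA5 (-0.56 ± 0.10), TLNRD1 (-0.56 ± 0.11), WIPF1 (-0.45 ± 0.10) and BCAT1 (-0.42 ± 0.09) fell as well. NGFR (1.00 ± 0.527 to 3.85 ± 2.91 CPM, adjusted p = 0.673), EGFR (2.79 ± 0.612 to 4.59 ± 0.28, adjusted p = 0.57) and DOT1L (-0.09 ± 0.07, adjusted p = 0.638) were not called.

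Of 41 DNA replication genes, 1 fell in low cells (10 when adjusted over the list alone; median -0.09, adjusted p = 7.88e-06, or adjusted p = 0.247 with an estimated correlation), the helicase subunit MCM2 (-0.20 ± 0.05). Of 29 glycolysis genes, 1 fell (7 when adjusted over the list alone; median -0.08, adjusted p = 0.00887, or adjusted p = 0.757 with an estimated correlation), the hexokinase HK2 (510 ± 12.2 to 415 ± 18.4 CPM). Of 36 receptor tyrosine kinases and ligands, MET rose (18.4 ± 1.16 to 29.4 ± 1.24 CPM) and IGF1R fell (-0.31 ± 0.06), 1 and 1 also when adjusted over the list alone (median 0.29, or 0.25 with a gene at 0 counts set to its bound, adjusted p = 0.0268). Of 22 TGF-beta genes 1 rose (4 when adjusted over the list alone; median 0.18, adjusted p = 0.0197), ID3 (0.98 ± 0.19). Of 37 interferon genes 2 rose (2 when adjusted over the list alone; median 0.18, adjusted p = 0.0283), GBP1 (1.14 ± 0.21) and CMPK2 (0.81 ± 0.18). Of 15 neuronal genes SCN3A rose (1.31 ± 0.32; 1 when adjusted over the list alone; median 0.27, adjusted p = 0.0268), and of 23 AP-1 genes none was called over all genes (3 rose when adjusted over the list alone; median 0.14, adjusted p = 0.0205). These 5 lists had an adjusted p = 0.838 with an estimated correlation.

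Among 6 endothelial markers, VWF rose (1.96 ± 0.487 to 4.02 ± 0.0383 CPM; 2 rose when adjusted over the list alone), with a median of 1.00 and an adjusted p of 0.000708, or adjusted p = 0.0446 with an estimated correlation. Of 16 replication-dependent histone genes, whose RNA mostly lacks poly(A) tails, 1 rose (4 when adjusted over the list alone; median 1.78, adjusted p = 7.15e-08, or adjusted p = 0.76 with an estimated correlation), H2BC11 (1.11 ± 0.323 to 3.65 ± 1.13 CPM). EPZ5676 low replicate 1 held 23.93% of reads on no feature against 13.20% to 15.17% in DMSO low libraries; without the libraries with a high share the histone median was 0.67. Pigmentation genes (1 of 25 fell, 1 when adjusted over the list alone, BCL2A1 at -0.41 ± 0.10; median 0.02, adjusted p = 0.988), resistance markers (0 of 15, median 0.30, adjusted p = 0.157) and fibroblast markers (0 of 8, median 0.46, adjusted p = 0.198) were not called. Of the 9 genes in the list of DOT1L and its partners AFF3, a subunit of elongation complexes, rose (0.44 ± 0.09, adjusted p = 0.0109). The list was not called (adjusted p = 0.6). In all, 188 genes changed, 129 higher and 59 lower, with 44 and 0 at least 2-fold. Without DMSO bulk replicate 1 in the shared spread 968 did, including all 188, and without the 6 libraries with a high no-feature share 7. Of those 6 only EPZ5676 low replicate 1 is part of this comparison. Leaving out that library alone kept 90 of the 188 calls, and the no-feature share as a covariate kept 146. Of the 27 called genes named for this comparison, 9 kept their call with each single library left out, CD22, TRIM67, SCUBE2, PLEKHA7, RNF182, HTR7, SCRN1, MET and GBP1. Known changes of 1.5, 2 and 4-fold were found for 46.3%, 68.7% and 93.9% of genes, with 6.71% false calls.

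The interaction asks whether the EPZ5676 effect differed between high and low cells, or equally whether the high-to-low difference changed. MBP, a myelin protein, went from 485 ± 13.3 to 325 ± 15.5 CPM in high and from 237 ± 11.7 to 331 ± 3.05 in low cells with EPZ5676, an interaction of -1.06 ± 0.11 (adjusted p = 7.19e-05). The transcription factor ETS1 went from 163 ± 4.45 to 228 ± 12.1 CPM in high and from 278 ± 1.88 to 252 ± 7.12 in low cells (0.62 ± 0.07, adjusted p = 0.000125). The haem-degrading enzyme HMOX1 (0.83 ± 0.13, adjusted p = 0.00336), NRXN3 (1.05 ± 0.20), FRZB (1.26 ± 0.25), SPTB (1.27 ± 0.27), TMC8 (1.31 ± 0.27) and CAPN3 (2.47 ± 0.48) had positive interactions. ITGA7 (-1.2 ± 0.16, adjusted p = 0.00227), COL14A1 (-0.92 ± 0.14, adjusted p = 0.00336), the laminin LAMA5 (-1.44 ± 0.29), MLPH (-0.44 ± 0.07) and FAIM2 (-3.08 ± 0.58) had negative ones. NGFR (-1.64 ± 1.76, adjusted p = 0.784), EGFR (-0.99 ± 0.53, adjusted p = 0.533) and DOT1L (-0.09 ± 0.10, adjusted p = 0.785) were not called.

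The DNA replication list moved most by its test: 2 of 41 genes had a positive interaction (17 when adjusted over the list alone; median 0.17, adjusted p = 6.36e-10, or adjusted p = 0.0894 with an estimated correlation), GINS2 (0.47 ± 0.10) and UNG (0.41 ± 0.09). Ribosomal proteins (0 of 50; 2 when adjusted over the list alone; median 0.18, adjusted p = 1.63e-06) and pigmentation genes (1 of 25 positive, 1 negative; 3 and 1 when adjusted over the list alone; median 0.28, adjusted p = 0.00123) were positive. AP-1 genes (0 of 23; 1 negative when adjusted over the list alone; median -0.40, adjusted p = 0.00322), MAPK output (DUSP4 at -0.36 ± 0.08, 1 of 20 negative; 3 when adjusted over the list alone; median -0.19, adjusted p = 0.00398), TGF-beta genes (0 of 22, median -0.23, adjusted p = 0.0265), mitosis (0 of 52, median -0.07, adjusted p = 0.0442) and resistance markers (0 of 15, median -0.60, adjusted p = 0.0442) were negative. So were histones (0 of 16, median -1.37, adjusted p = 0.00219) and endothelial markers (0 of 6, or 2 negative when adjusted over the list alone, median -1.23, adjusted p = 0.0265, or adjusted p = 0.251 with an estimated correlation). Summed histone CPM was 166 in DMSO high replicate 3 against 70.8 and 54.4 in replicates 1 and 2. It was 136 in EPZ5676 low replicate 1 against 59.3 and 61.7 in replicates 2 and 3. Libraries with a high no-feature share thus held more histone RNA and fall unevenly over the groups, so the histone interaction cannot be read as treatment alone. The other 8 lists had an adjusted p = 0.715 with an estimated correlation. DOT1L partners (0 of 9, median -0.08, adjusted p = 0.292) and fibroblast markers (0 of 8, median -0.60, adjusted p = 0.646) were not called. In all, 58 genes passed, 37 positive and 21 negative, with 7 and 8 at least 2-fold. Without DMSO bulk replicate 1 in the shared spread 1072 did, including all 58. With the no-feature share as a covariate 40 of the 58 kept their call. Without the 6 libraries with a high share EPZ5676 high cells were 1 library, so that fit does not weigh the calls. Of the 16 called genes named here, 6 kept their call with each single library left out, ETS1, HMOX1, MBP, ITGA7, COL14A1 and MLPH. Across genes, which are not independent replicates, the EPZ5676 effects in high and in low cells correlated with r = 0.21 and rho = 0.15. Known changes of 1.5, 2 and 4-fold were found for 19.4%, 52.2% and 78.8% of genes, with 2.91% false calls.

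**Figure D3:**
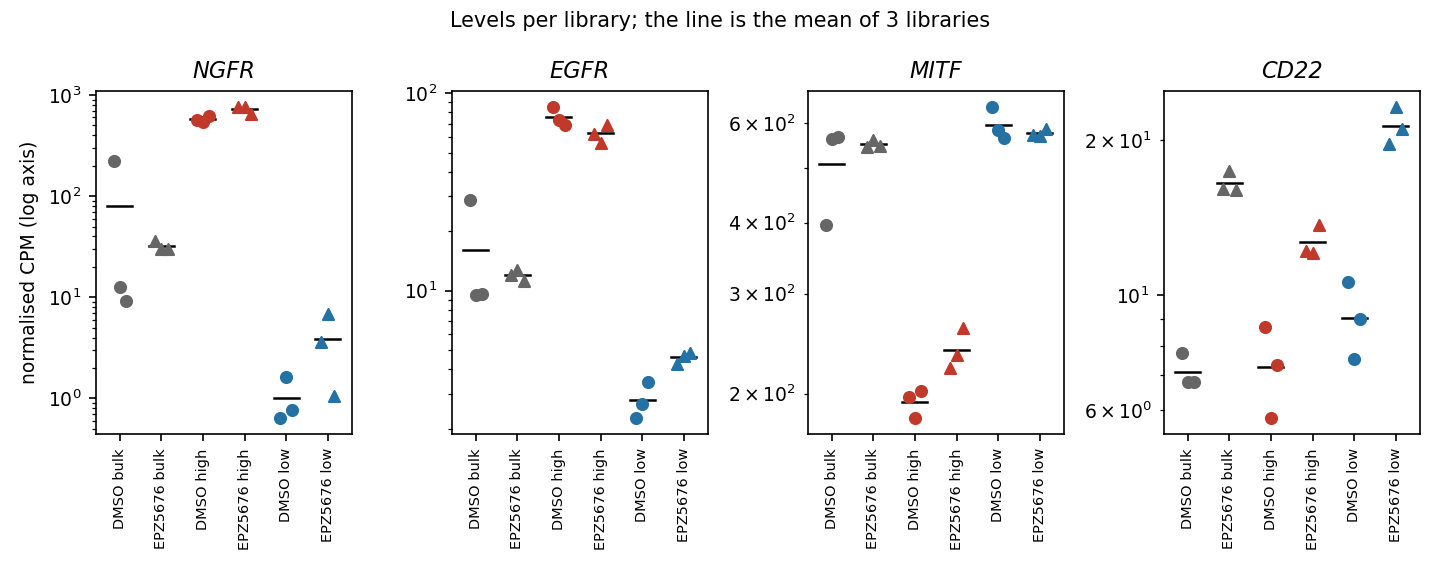
Normalised CPM of NGFR, EGFR, MITF and CD22 in each library on a log axis, by group, with the mean of 3 libraries as a line. NGFR was 220 CPM in DMSO bulk replicate 1 against 12.6 and 9.24 in the other DMSO bulk libraries, and 35.7, 29.9 and 30.3 in EPZ5676 bulk libraries.

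The comparison of EPZ5676 with DMSO in bulk asks what DOT1L inhibition changed in the unsorted culture. CD22 rose from 7.11 ± 0.541 to 16.5 ± 0.792 CPM (1.22 ± 0.14, adjusted p = 6.6e-05), and SCRN1 fell from 153 ± 11 to 106 ± 4.82 (-0.53 ± 0.06, adjusted p = 6.6e-05). CYP26B1 (1.01 ± 0.14), C11orf96 (1.09 ± 0.14), NMRK2 (1.65 ± 0.34), ZNF114 (1.48 ± 0.27), the kinase PRKCB (1.09 ± 0.21) and the semaphorin receptor PLXNA2 (1.09 ± 0.23) rose. POU3F2 (-0.46 ± 0.08), the chromatin protein HMGA2 (105 ± 28.3 to 65.6 ± 3.47 CPM), the DNA sensor CGAS (-0.46 ± 0.10), RHBDL1 (-0.88 ± 0.20), CRYBG1 (-0.64 ± 0.13) and WIPF1 (-0.53 ± 0.10) fell. NGFR stood at 80.7 ± 121 and 31.9 ± 3.22 CPM with DMSO and EPZ5676 (-1.33 ± 0.90, adjusted p = 0.602). EGFR stood at 16 ± 11.2 and 12 ± 0.755 CPM (-0.39 ± 0.34, adjusted p = 0.705). These changes were 1.55 for NGFR and 0.33 for EGFR without DMSO bulk replicate 1. DOT1L was not called (-0.25 ± 0.07, adjusted p = 0.0884). Of the 9 genes in the list of DOT1L and its partners AFF3 rose (0.53 ± 0.09, adjusted p = 0.00442). When adjusted over the list alone 1 rose and 1 fell (list adjusted p = 0.831).

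Of 30 extracellular matrix genes, SPARC rose (0.34 ± 0.05, 1 when adjusted over the list alone), while the list's median was -0.47 (adjusted p = 0.0312, or adjusted p = 0.93 with an estimated correlation). With the replicate number as a block the list no longer passed (adjusted p = 0.0554). COL1A1 stood at 107 ± 158 and 19.2 ± 2.25 CPM (-2.47 ± 0.89, adjusted p = 0.288). DMSO bulk replicate 1 moved with this list: without it the list's direction was upward (adjusted p = 8.85e-12) and COL1A1 was at 0.33. Of 15 resistance markers none was called over all genes (1 rose when adjusted over the list alone; median -0.54, adjusted p = 0.134), with WNT5A at -1.96 ± 0.83 and NRG1 at 0.75 ± 0.22. Without that library the resistance list was upward (adjusted p = 1.07e-07) and WNT5A was at 0.25. The 8 fibroblast markers were not called (1 rose when adjusted over the list alone; median -1.26, adjusted p = 0.471, or upward with an adjusted p of 0.00016 without that library, or 0.0529 with an estimated correlation as well).

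Of 25 pigmentation genes none was called over all genes or when adjusted over the list alone (median 0.14, adjusted p = 0.00302, or adjusted p = 0.644 with an estimated correlation), with DCT at 0.86 ± 0.25 and PMEL at 0.69 ± 0.24. Of 20 MAPK output genes DUSP4 fell (-0.26 ± 0.06; 2 fell when adjusted over the list alone; median -0.20, adjusted p = 0.00302, or adjusted p = 0.771 with an estimated correlation). Of 32 oxidative phosphorylation genes PPARGC1A rose (0.84 ± 0.14; 1 when adjusted over the list alone; median 0.08, adjusted p = 0.00292, or adjusted p = 0.771 with an estimated correlation). Mitosis (0 of 52, median -0.08, adjusted p = 0.00529, or adjusted p = 0.771 with an estimated correlation) and sterol synthesis (0 of 25, median -0.10, adjusted p = 0.0271, or adjusted p = 0.848 with an estimated correlation) passed as lists. Pigmentation, MAPK output, oxidative phosphorylation, mitosis and sterol synthesis no longer passed without DMSO bulk replicate 1. DNA replication (0 of 41, median -0.07, adjusted p = 0.00598) and glycolysis (0 of 29; 7 fell and 1 rose when adjusted over the list alone; median -0.13, adjusted p = 0.00763) had an adjusted p = 0.644 with an estimated correlation. Of 16 histone genes none was called over all genes (4 rose when adjusted over the list alone; median 2.19, adjusted p = 1.23e-11, or adjusted p = 0.644 with an estimated correlation), with H2BC11 at 1.4 ± 0.38 and H2BC21 at 1.12 ± 0.31. EPZ5676 bulk replicates 1 and 3 held 22.68% and 28.65% of reads on no feature, and without the libraries with a high share the histone median was 0.31, from EPZ5676 bulk replicate 2 alone. Endothelial markers (0 of 6; 1 rose when adjusted over the list alone) had a median of 0.68 (adjusted p = 0.00725, or adjusted p = 0.215 with an estimated correlation).

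In all, 132 genes changed in bulk, 90 higher and 42 lower, with 25 and 0 at least 2-fold. Without DMSO bulk replicate 1 the count was 550 (371 higher, 179 lower), including 125 of the 132. With the no-feature share as a covariate it was 50, and without the 6 libraries with a high share edgeR called 0. Of the 18 called genes named for this comparison, 7 kept their call with each single library left out, CD22, C11orf96, CYP26B1, SCRN1, AFF3, PPARGC1A and SPARC. Known changes of 1.5, 2 and 4-fold were found for 40.3%, 61.2% and 78.8% of genes, with 4% false calls.

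The bulk effect was also set against the high-to-low difference in DMSO, which shares no library with it, to ask whether genes of the high population moved with the inhibitor. Across genes, which are not independent replicates, r was -0.24 and rho -0.27, and r was 0.31 without DMSO bulk replicate 1. The 2321 genes at least 2-fold higher in high cells had a median bulk change of -0.18 (adjusted p = 0.00143; 6 rose, 2 fell), and the 1095 genes at least 2-fold lower had 0.18 (adjusted p = 1.75e-20; 25 rose, 0 fell). With an estimated correlation their adjusted p-values were 0.604 and 0.192. The medians were 0.26 (adjusted p = 2.3e-15; 211 rose, 2 fell) and 0.03 (adjusted p = 0.637) without DMSO bulk replicate 1.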

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

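Several tests were chosen only after the result was seen. They were those of DMSO bulk replicate 1, of the histone genes, of high cells in the EPZ5676 low sort and of the change in low cells. So were the EPZ5676 bulk libraries as a measure for the tolerance and the test of a trend with the no-feature share. The other tests of the smaller high-to-low difference were set before their own results, but after the data had been examined. They use genes chosen on DMSO bulk replicate 1 or leave out the 6 libraries with a high no-feature share. The splits were set before. The test of the difference itself, the interaction of treatment and sort, singled out 58 genes whose EPZ5676 effect differed between high and low cells. Among them the interaction was 1.31 for TMC8, 1.27 for SPTB, 1.26 for FRZB, 1.05 for NRXN3, 0.83 for HMOX1, 0.62 for ETS1, 2.47 for CAPN3, 0.47 for GINS2 and 0.41 for UNG. It was -3.08 for FAIM2, -1.44 for LAMA5, -1.2 for ITGA7, -1.06 for MBP, -0.92 for COL14A1, -0.44 for MLPH and -0.36 for DUSP4. Of 100 splits of the libraries, 2 gave as many genes, the real one included, with 59 in the highest other. For lists 4 splits gave as many as the real 10, with 11 in the highest other. Both shares are under 0.05. The other splits mix DMSO and EPZ5676 libraries within a sort, which puts any treatment effect into the spread. They therefore cannot exclude chance for the interaction alone.

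The high-to-low difference was smaller with EPZ5676: the 2321 genes at least 2-fold higher in DMSO high cells had a median of 1.89 under DMSO and 1.49 under EPZ5676, and the 1095 lower genes -1.57 and -1.26. Choosing genes on the sorts they are tested in is argued against, since 435 genes chosen on DMSO bulk libraries alone had a median interaction of -0.47 (bootstrap SE over genes 0.025). Every bootstrap SE in this section comes from drawing genes, which are not independent replicates. It does not measure the spread between libraries, so the readings here hold for these libraries only. A trend with the no-feature share is argued against by a median of -0.47 (SE 0.027) with the share as a covariate; without the 6 libraries with a high share it was -0.48, but EPZ5676 high cells were then 1 library, which excludes nothing. The 435 genes had a median change of -0.21 in high cells, where 72% were below 0. In low cells their median was 0.30 (SE 0.02), with 19.1% below 0. Low cells in the EPZ5676 high sort leave the low sort as it is, so they are argued against as the whole cause. High cells in the EPZ5676 low sort stay open for the low-cell part. Lower and higher genes gave shares of -7.23% and 2.18%, a difference of -9.41 points (SE 1.9), beyond the 5 points set. High cells alone would not give both shifts. But a share as small as 2.18% would hardly move the lower genes, so another shift in them could hide it. For the high-cell part low cells in the high sort stay open: lower and higher genes gave low-population shares of 6.09% and 15.9%, a difference of -9.78 points (SE 1.72), but the 5 points set were too narrow in this direction, since the same genes gave 7.5 to 10.6 points more high-population RNA from lower than from higher genes in the EPZ5676 bulk libraries. A narrowing of the difference by DOT1L inhibition may also be the cause, as a hypothesis found and tested on the same data.

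DMSO bulk replicate 1 lay between the high and low populations. A plain mixture with cells like the DMSO high sort is argued against. With DMSO bulk replicates 2 and 3 as the low end, 495 genes higher in high cells implied a share of 36.6% of high-population RNA. The 164 lower genes implied 63.5%, a difference of 27 points (bootstrap SE over genes 1.29). A library of another group under this label is argued against by its distance of 41.7 on the first principal component to the nearest library, where the widest range inside another group was 5.1. Depth or reads on no feature are argued against by its share of 13.83%, inside the 12.8% to 15.17% of 11 other libraries, and its 16270501 counts. A sample from outside the 6 groups, or a culture in another state, stays open and was not tested, and no biological explanation was tested.

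The list of replication-dependent histones passed upward with EPZ5676 in bulk (0 of 16 genes called, adjusted p = 0.644 with an estimated correlation) and low cells (1 of 16, adjusted p = 0.76 with an estimated correlation). Weaker poly(A) selection in the libraries with a high no-feature share is a candidate explanation: without them the median of 15 histone genes was 0.67 in low cells (1.68 with all libraries) and 0.31 in bulk (1.93 with all), where 1 EPZ5676 library, replicate 2, was left. The non-polyadenylated 7SK RNA, chosen after its values were seen, stood at 148 to 340 CPM in those 6 libraries and 0.143 to 1.9 CPM in the other 12. An effect of treatment in low cells stays open too, with a lower quartile of 0.42 in the remaining libraries. Of the 6 libraries 5 were EPZ5676 libraries.

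For 3 libraries against 3 there are 10 splits, which cannot give a share under 0.1. The numbers of genes in the real and in the highest other split were 132 and 8 in bulk, 543 and 0 in high cells, 188 and 0 in low cells, 10199 and 44 for high against low under DMSO, and 8858 and 0 under EPZ5676, each with 1 split as large, the real one. For lists they were 10 and 19 in bulk (10 of 10 splits as large), 9 and 6 in high cells (1 of 10), 9 and 4 in low cells (1 of 10), 18 and 19 for high against low under DMSO (2 of 10) and 17 and 19 under EPZ5676 (6 of 10). In bulk every split gave at least 10 lists. Wrong splits of high against low gave up to 19 lists as well, so such counts do not by themselves name the source. The bulk split with 19 put DMSO bulk replicate 1 with EPZ5676 bulk replicates 1 and 3, which have a high no-feature share.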

How the results depend on the processing

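The alternatives that used the no-feature share, or left DMSO bulk replicate 1 out of the shared spread or together with another choice, were chosen after seeing the data. The counts of changed genes for bulk, high cells, low cells and the interaction were 440, 948, 373 and 304 with no filter, where more genes were tested. They were 2, 1413, 1028 and 863 with only the groups compared, with 668 higher and 745 lower in high cells. Without the 6 libraries with a high no-feature share edgeR called 0 (754 at an unadjusted p under 0.05), 5, 7 and 0 (784 unadjusted), and 4176 for high against low under EPZ5676, from fewer libraries; DESeq2 and limma-voom were not run on those. Without the 6 libraries EPZ5676 bulk and EPZ5676 high cells were 1 library each, so the counts that use them do not weigh the calls. With all libraries DESeq2 called 290 in bulk, 317 in low cells and 177 for the interaction. Estimation that was not robust gave 35 for the interaction. Without DMSO bulk replicate 1 in the shared spread 2018 genes were called in high cells, 968 in low cells and 1072 for the interaction. In bulk the no-feature covariate gave 50 genes, with the replicate block as well 26, and with DMSO bulk replicate 1 left out 419.

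With DMSO bulk replicate 1 left out and the covariate, NGFR was 1.44 in bulk, EGFR 0.47 (adjusted p = 0.0358), WNT5A 0.29 and COL1A1 0.39, all of the opposite sign, as was the correlation with the high-to-low difference (0.28) and the median of genes higher in high cells (0.27, adjusted p = 8.44e-16); the median of lower genes was 0.02 (adjusted p = 0.919). NGFR in bulk was 0.24 with limma-voom. With an estimated correlation the set medians of -0.18 and 0.18 had adjusted p-values of 0.604 and 0.192, and with fry 0.604 and 0.117. The correlation of EPZ5676 effects between high and low was 0.13 without the 6 libraries.

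With an estimated correlation 0 lists passed camera in bulk, high cells, both high-to-low comparisons and the interaction, and 1 in low cells. Fry called 1, 1, 2 and 1 in bulk, high cells, low cells and the interaction, and 25 and 23 for high against low under DMSO and EPZ5676. Its list in high cells (upward, fry adjusted p = 0.0302) and in the interaction (positive, 0.000986) was DNA replication. In low cells fry called DNA replication (downward, 0.00655) and endothelial markers (upward, 0.00545), and in bulk endothelial markers (upward, 0.0378). A mean of at least 5 CPM left 5 lists in low cells. In bulk 4 lists passed with the covariate, 5 without the 6 libraries and 16 with DMSO bulk replicate 1 left out and the covariate, and in high cells 4 without the 6 libraries, none of them downward. Except where named, the cause was not tested.

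Leaving out each library in turn gave 39 to 550 genes in bulk, 200 to 327 in high cells, 60 to 107 in low cells, 14 to 46 for the interaction, 9474 to 9812 for high against low under DMSO and 8033 to 8123 under EPZ5676. Lists ranged from 8 to 18, 7 to 10, 6 to 9, 7 to 10, 17 to 19 and 16 to 19. The bulk correlation ran from -0.38 to 0.31, the correlation between high and low from 0.14 to 0.36, and the set medians from -0.35 to 0.26 and from 0.03 to 0.29. NGFR in bulk ran from -1.86 to 1.55, EGFR from -0.66 to 0.33, WNT5A from -2.47 to 0.25 and COL1A1 from -3.0 to 0.33. The upper ends of these 4 genes and of the bulk counts, and the turned signs, came without DMSO bulk replicate 1.

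With the replicate number as a block 129, 525, 173, 10117, 8792 and 49 genes changed in bulk, high cells, low cells, high against low under DMSO and EPZ5676, and the interaction. The numbers were not shown to pair the libraries: 8 of 45 correlations between like-numbered libraries were over 0.1 (range -0.34 to 0.30, median -0.01). With RLE factors, library size alone or a mean of at least 5 CPM all 6 counts of genes stayed within 1.5 times, but with library size alone the lower genes were more than the higher for high against low, 5564 and 4746 under DMSO and 4931 and 4067 under EPZ5676. Leaving out mitochondrial genes was not run, since they had 0 counts. The lowest depth was 13383741 counts, and its effect on the calls was not tested.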

Other observations

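The comparisons of lists with an estimated correlation and without DMSO bulk replicate 1 together, and the share of high-population RNA in bulk, were chosen only after the result was seen. Heat shock genes were not called as a list between the sorts (6 of 15 higher and 5 lower under DMSO, adjusted p = 0.812), and neither were p53 targets (11 of 25 higher, 9 lower, median 0.08, adjusted p = 0.406) nor HOXA and MEIS genes (3 of 12 higher, 1 lower, median 0.27, adjusted p = 0.424). Within heat shock genes the inducible HSPA1B (1.32 ± 0.09) and HSPA1A (1.14 ± 0.12) were higher in high cells and HSP90AA1 (-0.96 ± 0.10) and HSPD1 (-0.94 ± 0.09) lower. Among p53 targets DDB2 (1.03 ± 0.13) and PMAIP1 (1.2 ± 0.14) were higher and GDF15 (-1.29 ± 0.13) lower, and MEIS3 was higher (2.75 ± 0.28). These genes were chosen after their values were seen. Known target genes of DOT1L in leukaemia, HOXA and MEIS genes, were not called as a list with EPZ5676 in bulk (0 of 12, adjusted p = 0.832), high cells (0 of 12, adjusted p = 0.651) or low cells (0 of 12, adjusted p = 0.475).

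Keratinocyte and leukocyte markers had 3 tested genes each and were not tested as lists. As means over all 18 libraries, their most abundant genes were KRT10 at 33.8 CPM and FCER1G at 3.49 CPM. The fibroblast marker COL1A1 had 242 CPM and the endothelial marker EGFL7 24.2 CPM. COL1A1 was far higher in the high than in the low sort, so its mean does not describe each group. Of 15 mitochondrially encoded genes 0 had a count.

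Without DMSO bulk replicate 1 and with an estimated correlation, 7 lists were upward with EPZ5676 in bulk: resistance markers (adjusted p = 0.00992), receptor tyrosine kinases (adjusted p = 0.00992), TGF-beta genes (adjusted p = 0.0105), extracellular matrix (adjusted p = 0.0105), the undifferentiated state (adjusted p = 0.0119), NF-kB genes (adjusted p = 0.0139) and endothelial markers (adjusted p = 0.0309). With the low sort of the same treatment as the low end, genes higher in high cells gave a median share of high-population RNA of 38.7%, 2.52% and 2.86% in DMSO bulk replicates 1, 2 and 3, and of 6.94%, 5.46% and 5.6% in the EPZ5676 bulk libraries. Genes lower in high cells gave 68.2%, 10.8%, 11.1%, 13.7%, 11.9% and 13.2%.

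The share of reads on no feature was 18.9% ± 5.63 (SD, n = 9) in EPZ5676 and 14.7% ± 2.61 (n = 9) in DMSO libraries, a difference of 4.16 points (exact permutation p = 0.0676 over 48620 splits).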
